A study of Bos taurus with 9 samples.

How the data were processed

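Transcripts of bovine endometrial epithelial cells (BEEC) were measured in 9 libraries, 3 for each of the groups control, HIGHGLUC and LOWAA, named after the regime in which the co-cultured embryos had been kept. Per the labels the RNA was total RNA of cells pooled from 3 wells, sequenced as single reads of 50 bp on an Illumina HiSeq2000. The table's headers call the libraries paired, and the labels give passage 1 in the protocol and passage 2 in the sample fields; neither difference enters a computation here. Per the labels Bowtie2, HTSeq 0.5.4p2 and the genome build UMD3.1 were used, without the role of each tool.

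A single deposited table with 24596 genes and 231 columns held all values. Per the file headers its total exon reads, unique exon reads, intron reads and exon-exon reads are raw read counts per gene, and total exon reads include reads that match several places. The signal columns deposited as normalised expression values were quantile normalised by the authors, since the 9 libraries had identical sorted values. The RPKM columns deposited by the authors give total exon reads per kilobase of exon, scaled to the sum of exon and intron reads of the library. The authors' weighted proportions fold change is a signed score, negative for a fall. The p-value columns of the authors hold the p-value of Baggerley's test and its FDR correction, on the quantile normalised values. The exon length, chromosome and gene positions are other deposited columns, which describe the annotation. The computations here read 67 columns, and 140 columns of library values were not used. Gene names are those of the table, where 6055 of the 24596 genes carry an Ensembl identifier instead of a symbol. For 3989 genes the table lists an exon length of 0, so no read could be counted in their exons.

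Total exon reads were the values compared. They ranged from 2887097 in control replicate 5 to 13969325 in control replicate 9. A count of 0 allows up to 3 reads, which is 0.215 to 1.04 CPM (read counts scaled to the exon reads of the library) depending on the library. Such limits and the 95% Wilson intervals given for shares of reads cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. Gene levels are CPM with TMM factors in the comparisons and plain CPM for cell type markers. Pairs of libraries in the same group differed by 8.67 to 28.1 chi-square units per degree of freedom, so no library duplicated another.

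Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 11839 genes, 10410 of them with a symbol. Counts were scaled with TMM and tested with the robust quasi-likelihood test of edgeR in R 4.3.3, with all 9 libraries in 1 fit and the group as the only term. The 3 pairwise comparisons and the test over all groups came from that fit, with Benjamini-Hochberg adjusted p at a threshold of 0.05. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with a correlation estimated for each list. Of the lists 26 had at least 3 tested genes, which with 3 comparisons made 78 tests adjusted together, and 5 lists of cell type markers had at most 2 and were not tested. A list score is the mean log2 CPM of its members, compared between groups with an exact two-sided permutation test, for which 3 libraries against 3 give 10 splits and no p below 0.10. The groups, tests, gene lists and most alternatives were chosen before the data were examined.

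The library numbers fall into 3 runs with 1 library of each group, called sets here. In an alternative fit the sets were a further term. Before they could be treated as pairs, libraries of a set had to correlate with each other above 0.1 after removal of the group means. With total exon reads 7 of 9 such pairs did, and the lowest value was 0.022, so the fit without sets was kept for the main counts. With unique exon reads, chosen after seeing the data, 9 of 9 pairs did, from 0.198 to 0.452, beside -0.367 to 0.032 for the 18 other pairs. The pairs under 0.1 with total exon reads were HIGHGLUC replicate 10 with control replicate 9 and with LOWAA replicate 12 (0.047 and 0.022). With unique exon reads these had 0.363 and 0.371. Replicate 10 had 5.20% multiply matched reads, against 4.27% and 4.14% in replicates 9 and 12. The choice of the fit without sets thus rested on pairs with this library. The biological coefficient of variation was 0.171 without sets and 0.107 with them. With unique exon reads it was 0.113 without sets and 0.0722 with them. Residual degrees of freedom were 6 and 4.

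Genes named in the text followed a rule. For each comparison they were the 12 with the largest rise and fall among genes that passed, had a symbol, a mean of at least 2 CPM and no overlap between groups. Where fewer passed, those with the smallest p made 6 per direction, and each list added up to 4 members with the smallest p. Genes called by DESeq2 or with the sets as a term are named besides, chosen after their values were seen. The tests were tried on simulated counts with known changes of 1.5, 2 and 4-fold in a share of genes and the same depths. The interferon list was lowered in LOWAA there as well, and its genes were left out of the counts of changed and unchanged genes. False calls were counted over 10 simulated data sets.

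Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, no filter, a filter at 2 CPM, a surrogate variable from sva 3.50.0, a fold threshold of 1.2, fits of 6 libraries, and leaving out each library in turn. Alternatives chosen after seeing the data were unique exon reads, a term for the split of the libraries by multiply matched reads, limma-trend on the deposited normalised values, and all variations of the fit with sets and of the medians of the lists. Intron reads were not used in the main comparisons and were tested separately. The counts of called genes are complete, but not every called gene is named, and 2 genes are not reported here.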

Results

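RNA was sequenced from bovine endometrial epithelial cells (BEEC), primary cells scraped from the inner surface of the uterus, after co-culture with embryos. Groups of 5 morulae were placed on the monolayers at day 4 after fertilisation and stayed until day 8, when the BEEC were harvested and 3 wells were pooled. The embryos had been pre-conditioned beforehand, and the labels name the regimes control, HIGHGLUC and LOWAA without concentrations. The names read as high glucose and low amino acids. Each group held 3 libraries, which makes 9 libraries in all. The comparisons ask whether endometrial cells carry different transcripts after contact with embryos of a different nutrient history. The control group gave 2887097, 13969325 and 10330769 exon reads in replicates 5, 9 and 13. The HIGHGLUC group gave 9030731, 7513432 and 6927123 exon reads in replicates 6, 10 and 14. The LOWAA group gave 10398399, 7877596 and 9248075 exon reads in replicates 8, 12 and 15. Of 24596 genes in the table, 11839 had enough reads to be tested. In the order of library numbers, of which some are missing, each run of 3 libraries held 1 library of every group. Set 1 held replicates 5, 6 and 8, set 2 held 9, 10 and 12, and set 3 held 13, 14 and 15. A second number in the file headers ran without gaps, from 57 to 59, 60 to 62 and 63 to 65 in these sets. The labels do not say what the numbers mean, and they tie no library to a separate culture or animal. All p-values therefore measure only the spread between these libraries.

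**Figure D1:**
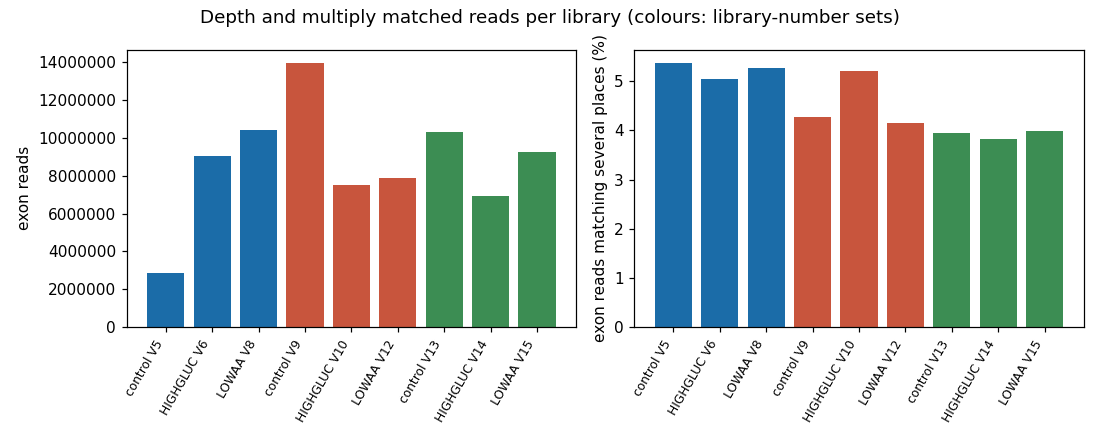
Exon reads per library (left) and the percentage of exon reads that matched several places (right), 1 bar per library, coloured by library-number set. Control replicate 5 was the shallowest library with 2887097 exon reads, and replicates 5, 6, 8 and 10 each had over 5% multiply matched reads.

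The cultures carried keratin transcripts together with matrix genes of stromal cells in every library. KRT8 had a mean of 4444 CPM, read counts scaled to the exon reads of the library, over the 9 libraries, with a range of 4256 to 4844. KRT18 had a mean of 1994 CPM and KRT19 of 1593 CPM. COL3A1, a fibrillar collagen, had 5085 CPM, the proteoglycan DCN had 2103 CPM and the intermediate filament gene VIM had 542 CPM. The epithelial adhesion gene CDH1 had 122 CPM and KRT7 had 150 CPM. EPCAM, another epithelial adhesion gene, had 13 reads in all libraries together, and CLDN7 and GRHL2 had 0 reads. The leukocyte gene PTPRC and the T cell gene CD3E had 0 reads in each library, which allows up to 0.215 CPM in the deepest library and 1.04 CPM in the shallowest. PTPRC and CD3E have exon lengths of 4157 and 1294 bases in the table, and CLDN7 and GRHL2 of 1214 and 1915, so their reads could be counted. The myeloid genes CD163 and CD14 had means of 8.61 and 5.27 CPM. Among embryo markers SOX2, with an exon length of 1460 bases, had 0 reads and IFNT2, an interferon of the trophectoderm, had 13 reads in all. GATA2 had 55.5 CPM and TEAD4 had 44.1 CPM, and neither gene is specific to embryos. None of the epithelial, stromal fibroblast and smooth muscle lists passed the list test in any comparison. The smooth muscle score was above the control in sets 1, 2 and 3, by 0.15, 0.42 and 0.26 for HIGHGLUC. For LOWAA it was above by 0.23, 0.30 and 0.02. Of its 5 members 2 were higher for HIGHGLUC and 5 for LOWAA.

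The first comparison asked what BEEC carried after contact with HIGHGLUC embryos rather than control embryos. Genes of the type I interferon response, the antiviral program that embryo interferon also switches on in the uterus, fell as a group. Of 38 tested members 36 were lower, with a median log2 fold change of -0.26 (camera adjusted p = 1.50e-14, adjusted p = 0.176 with an estimated correlation). The mitochondrially encoded genes rose as a group, with 12 of 12 members higher and a median of 0.22 (camera adjusted p = 0.000548, adjusted p = 0.939 with an estimated correlation). The cell cycle list fell, with 30 of 30 members lower and a median of -0.26 (camera adjusted p = 6.86e-05, adjusted p = 0.939 with an estimated correlation). The cholesterol synthesis list fell by a smaller amount, with 20 of 22 members lower and a median of -0.10 (camera adjusted p = 0.00782, adjusted p = 0.939 with an estimated correlation).

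Among interferon genes, CMPK2, a mitochondrial nucleotide kinase, had 79.6 ± 6.33 CPM with control embryos and 54.0 ± 4.68 CPM with HIGHGLUC embryos (SD, n = 3), a log2 fold change of -0.56 ± 0.14 (SE). ISG15, a ubiquitin-like modifier, had 782 ± 134 CPM against 611 ± 42.8 CPM, a log2 fold change of -0.36 ± 0.12. XAF1 had a log2 fold change of -0.36 ± 0.10 and OAS1X, an oligoadenylate synthetase, of -0.46 ± 0.14. The list score differed from the control by -0.30, -0.34 and -0.23 in sets 1, 2 and 3. An exact two-sided permutation test of the list score gave p = 0.10, the smallest value that 3 libraries against 3 allow. For the mitochondrial, cell cycle and cholesterol lists the same permutation test gave p = 0.30, 0.60 and 0.60. The correlation estimated between cell cycle genes was 0.924, far above the preset 0.01.

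Of the mitochondrial genes, cytb had 838 ± 261 CPM against 1156 ± 229 CPM, a log2 fold change of 0.46 ± 0.26, and COX3 had a log2 fold change of 0.34 ± 0.21. The score of the mitochondrial list was above that of the control by 0.21, 0.53 and 0.08 in sets 1, 2 and 3. Without control replicate 9 its median was 0.08 (camera adjusted p = 0.299) and without HIGHGLUC replicate 14 it was 0.14 (camera adjusted p = 0.109), while without control replicate 13 it rose to 0.43. The mitotic genes BUB1, CDC20 and DLGAP5 had log2 fold changes of -0.37 ± 0.25, -0.41 ± 0.29 and -0.54 ± 0.38. The cell cycle score differed by -0.63, -0.13 and -0.09 in sets 1, 2 and 3, and without HIGHGLUC replicate 6 the median was 0.01, of the opposite sign (camera adjusted p = 0.704). Without control replicate 9 the cell cycle median was -0.05 (camera adjusted p = 0.327), and without HIGHGLUC replicate 10 it was -0.58. In the cholesterol list NSDHL had a log2 fold change of -0.20 ± 0.09. The score of that list differed by -0.18, 0.00 and -0.17 in sets 1, 2 and 3. The cholesterol call was lost without control replicate 9, HIGHGLUC replicate 6 or HIGHGLUC replicate 14 (medians -0.044, -0.047 and -0.044, camera adjusted p = 0.439, 0.480 and 0.257), and the median was -0.165 without control replicate 5 and -0.253 without HIGHGLUC replicate 10.

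No single gene passed the test against the control. The 6 symbols with the smallest p among higher genes were DPYD, HIC1, SAMD4B, C11orf49, SLC29A1 and PLEKHB1. The pyrimidine-degrading enzyme gene DPYD, on chromosome 3 from 45563731 to 46487165, had 65.7 ± 4.33 CPM against 84.5 ± 8.24 CPM (SD, n = 3), a log2 fold change of 0.36 ± 0.10. HIC1, a transcriptional repressor gene, had 1.37 ± 0.04 CPM against 2.89 ± 0.56 CPM, a log2 fold change of 1.08 ± 0.30. SLC29A1, a nucleoside transporter gene, had a log2 fold change of 0.26 ± 0.08. Among lower genes the 6 were CMPK2, XAF1, PIGF, DEF6, ITGA6 and YARS. DEF6 had a log2 fold change of -0.60 ± 0.16, the laminin receptor subunit ITGA6 of -0.28 ± 0.08 and the tyrosyl-tRNA synthetase YARS of -0.35 ± 0.10. PIGF had -0.58 ± 0.16, and 70.7% of its reads matched a single place. With the library-number sets as a term its log2 fold change was -0.56, but -0.13 with unique exon reads (edgeR adjusted p = 0.917). Its fall thus rested largely on reads that match several places. The edgeR quasi-likelihood test called 0 of 11839 genes (smallest adjusted p = 1.00), with 353 genes at an unadjusted p under 0.05 where 592 would be expected by chance. Counts from limma-voom and DESeq2 were 0 as well. Adjusted over the list alone, 0 members of the interferon, mitochondrial, cell cycle and cholesterol lists passed without the library-number sets. With the sets as a term 24 of 38 interferon genes, all lower, and 10 of 12 mitochondrial genes, all higher, passed in that way, and 0 of the cell cycle and cholesterol lists. With the library-number sets as a term, 788 genes had an unadjusted p under 0.05 in edgeR, above the 592 expected by chance if its p-values are exact. They may run small. In a comparison with no change this fit made false calls in 10 of 10 simulated data sets, beside 3 of 10 without sets. After adjustment it called 3 genes: cytb rose, and the phospholipid transporter gene ATP8B4 and the calcium-binding protein gene S100A2 fell. In 10 simulated data sets the same fit called 3.60 unchanged genes on average and up to 8 in a comparison with no change, so these 3 calls are at the level of its false calls. The count was 0 without control replicate 5, control replicate 9 or HIGHGLUC replicate 10. It was 31 without control replicate 13, 19 without HIGHGLUC replicate 6, 13 without LOWAA replicate 12, 6 without HIGHGLUC replicate 14 and 5 without LOWAA replicate 15.

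The second comparison asked what BEEC carried after contact with LOWAA embryos rather than control embryos. The interferon list fell here too, with 36 of 38 members lower and a median log2 fold change of -0.31 (camera adjusted p = 3.02e-19, adjusted p = 0.171 with an estimated correlation). The mitochondrially encoded genes rose, with 12 of 12 members higher and a median of 0.31 (camera adjusted p = 4.77e-05, adjusted p = 0.939 with an estimated correlation). The endoplasmic reticulum chaperones rose by a small amount, with 15 of 17 members higher and a median of 0.12 (camera adjusted p = 0.00782, adjusted p = 0.939 with an estimated correlation). TXNIP, a glucose-responsive inhibitor of thioredoxin, had 393 ± 34.9 CPM with control embryos and 195 ± 27.7 CPM with LOWAA embryos (SD, n = 3).

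PARP14, a mono-ADP-ribosyltransferase induced by interferon and located on chromosome 1 from 67613091 to 67659266, had 452 ± 13.8 CPM against 300.2 ± 26.2 CPM, a log2 fold change of -0.59 ± 0.11 (SE). CMPK2 had a log2 fold change of -0.61 ± 0.14, ISG15 of -0.43 ± 0.12, and the RNA sensors IFIH1 and DDX58 of -0.43 ± 0.12 and -0.36 ± 0.09. Adjusted over the list alone, 17 of 38 interferon genes passed in edgeR, 16 lower and 1 higher, beside 0 adjusted over all genes, and with the sets as a term 30 passed, 29 lower and 1 higher. The higher gene was the chemokine CXCL9, with 15.4 ± 2.40 CPM against 21.9 ± 2.94 CPM and a log2 fold change of 0.50 ± 0.18. With the sets as a term, 5 interferon genes fell after adjustment over all genes in edgeR: PARP14 (adjusted p = 0.00844), ISG15 (0.0147), IFIH1 (0.0335), DTX3L (0.0430) and Mx1 (0.0475). The list score differed from the control by -0.29, -0.53 and -0.15 in sets 1, 2 and 3. The exact two-sided permutation test of its score gave p = 0.10, again the smallest value possible. For the mitochondrial and chaperone lists this permutation test gave p = 0.30 and 0.30.

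**Figure D2:**
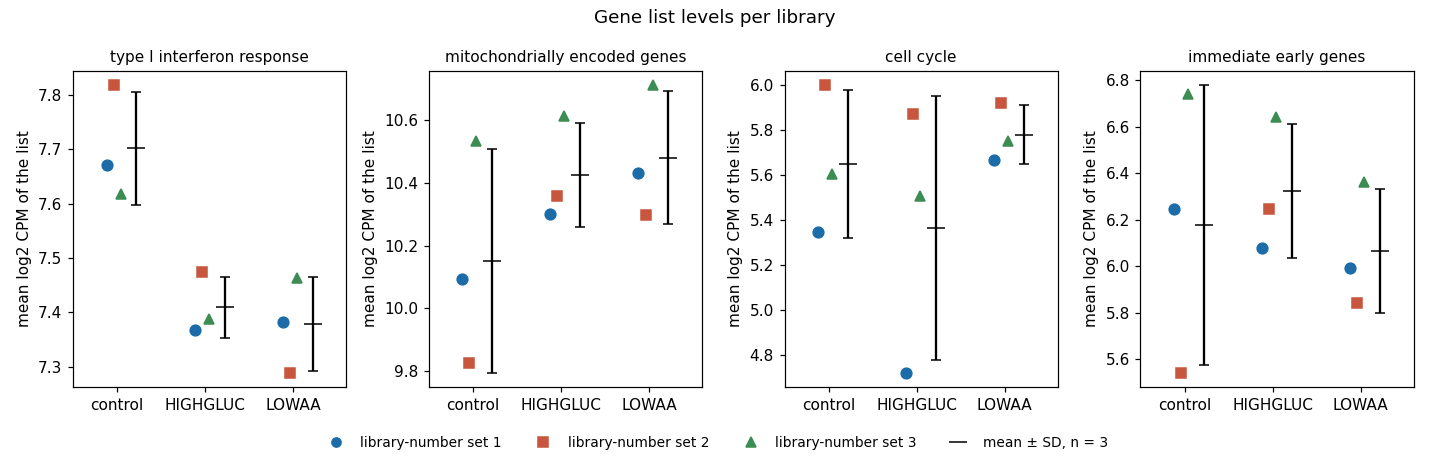
Mean log2 CPM of 4 gene lists in each library (vertical axes, which do not start at 0), by group, with symbols for the library-number sets and bars for the mean and SD of 3 libraries. The 3 control libraries lay above the 6 others for the interferon list, and HIGHGLUC replicate 6 lay lowest for the cell cycle list.

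Of the mitochondrial genes, cytb had a log2 fold change of 0.52 ± 0.26, ND5 of 0.42 ± 0.26, ND2 of 0.39 ± 0.18 and ND3 of 0.38 ± 0.15. Their list score was higher by 0.34, 0.47 and 0.18 in sets 1, 2 and 3. Without control replicate 9 the median was 0.17 (camera adjusted p = 0.122), without LOWAA replicate 15 it was 0.16 and without control replicate 13 it was 0.54. With the sets as a term, cytb, ND5 and ND3 rose after adjustment over all genes (edgeR adjusted p = 0.00150, 0.00844 and 0.0475). In the chaperone list CRELD2 had a log2 fold change of 0.44 ± 0.20, the stress-induced secreted factor MANF of 0.19 ± 0.09 and the transcription factor XBP1 of 0.20 ± 0.10. The chaperone score was higher by 0.16, 0.11 and 0.10 in sets 1, 2 and 3. That call was lost without control replicate 9, LOWAA replicate 8 or LOWAA replicate 15 (medians 0.043, 0.066 and 0.067, camera adjusted p = 0.339, 0.177 and 0.182), and without LOWAA replicate 12 the median was 0.218. Adjusted over the list alone, 0 members of the mitochondrial and chaperone lists passed without the sets, and 10 (all higher) and 0 with them.

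The amino acid response list, targets of the transcription factor ATF4, did not pass as a group against the control (11 of 29 members higher, median -0.02, camera adjusted p = 0.719). Its member CHAC1, which degrades glutathione, had 1.88 ± 0.35 CPM against 4.56 ± 0.75 CPM (SD, n = 3), a log2 fold change of 1.33 ± 0.33. CHAC1 was the 1 member that passed adjusted over the list alone. TXNIP was the 1 member of 17 in the glucose uptake and sensing list that did so, with a log2 fold change of -1.01 ± 0.19, and with the sets as a term 0 members did: TXNIP then had -1.02 ± 0.21, with an unadjusted p of 0.00476 rather than 0.000423 and 4 rather than 6 residual degrees of freedom. That list had a median of -0.02 (camera adjusted p = 0.735), and glycolysis had a median of -0.02 (camera adjusted p = 0.929). PLK3, a stress-responsive kinase, passed over the p53 target list alone, with a log2 fold change of 0.68 ± 0.17. The immediate early genes MYC and ZFP36 passed over their list alone, with log2 fold changes of -0.42 ± 0.11 and -0.83 ± 0.20. With the sets CHAC1, PLK3 and MYC still passed over their lists and ZFP36 (-0.83 ± 0.25) did not.

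The other symbols with the smallest p among higher genes were ERRFI1, SFRP5, ORMDL3 and NPR1. ERRFI1, a feedback inhibitor of the EGF receptor on chromosome 16 from 46201191 to 46215455, had 100.5 ± 6.94 CPM against 153 ± 6.96 CPM, a log2 fold change of 0.61 ± 0.11. SFRP5, a secreted inhibitor of Wnt signalling, had a log2 fold change of 0.52 ± 0.12. Among lower genes they were DLX2, HEY1, MED12L and MORC3. The homeobox gene DLX2 had a log2 fold change of -0.71 ± 0.13 and the Notch target HEY1 of -1.22 ± 0.26. The edgeR test called 0 of 11839 genes (smallest adjusted p = 0.711), with 474 at an unadjusted p under 0.05 where 592 would be expected. The limma-voom count was 0 and the DESeq2 count was 4: ERRFI1 rose (adjusted p = 0.00133), and PARP14 (0.00121), TXNIP (7.54e-05) and ZFP36 (0.0205) fell. Without HIGHGLUC replicate 6, edgeR called TXNIP alone (adjusted p = 0.0310).

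With the library-number sets as a term, 979 genes had an unadjusted p under 0.05 in edgeR, above the 592 expected by chance if its p-values are exact. After adjustment it called 19 genes in this comparison, 7 higher and 12 lower. Beside the interferon and mitochondrial genes, ERRFI1 rose (adjusted p = 0.00156), as did RASL11B, a small GTPase, with a log2 fold change of 1.00 ± 0.12, the SR protein gene SRSF5 (0.42 ± 0.08) and the pseudokinase TRIB1 (0.71 ± 0.12). ATP8B4 fell with a log2 fold change of -0.85 ± 0.11, DLX2 with -0.71 ± 0.14 and MYC with -0.43 ± 0.09. ZFP57 (-0.45 ± 0.08) and the deubiquitinase YOD1 (-0.75 ± 0.14) fell as well. In simulated data this fit recovered 65.7% of genes changed 1.5-fold. With 199 changed genes it called 18.3 unchanged genes on average and up to 27, which was 9.92% of its calls outside the interferon list there. That share does not carry over to 19 calls. The fit without sets recovered 28.4% of genes changed 1.5-fold, 80.3% at 2-fold and 95.5% at 4-fold. The rates of recovery of each fit come from a single simulated data set with 199 changed genes and do not carry over to few changes either. Without control replicate 5 or 9 the count with sets was 8 or 7, without HIGHGLUC replicate 6, 10 or 14 it was 30, 39 or 12, and without LOWAA replicate 8 or 12 it was 6 or 2. Of the 19 genes, 8, 6 and 11 were kept without control replicates 5, 9 and 13. Leaving out HIGHGLUC replicates 6, 10 and 14 kept 18, 19 and 11, and LOWAA replicates 8, 12 and 15 kept 6, 1 and 14.

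**Figure D3:**
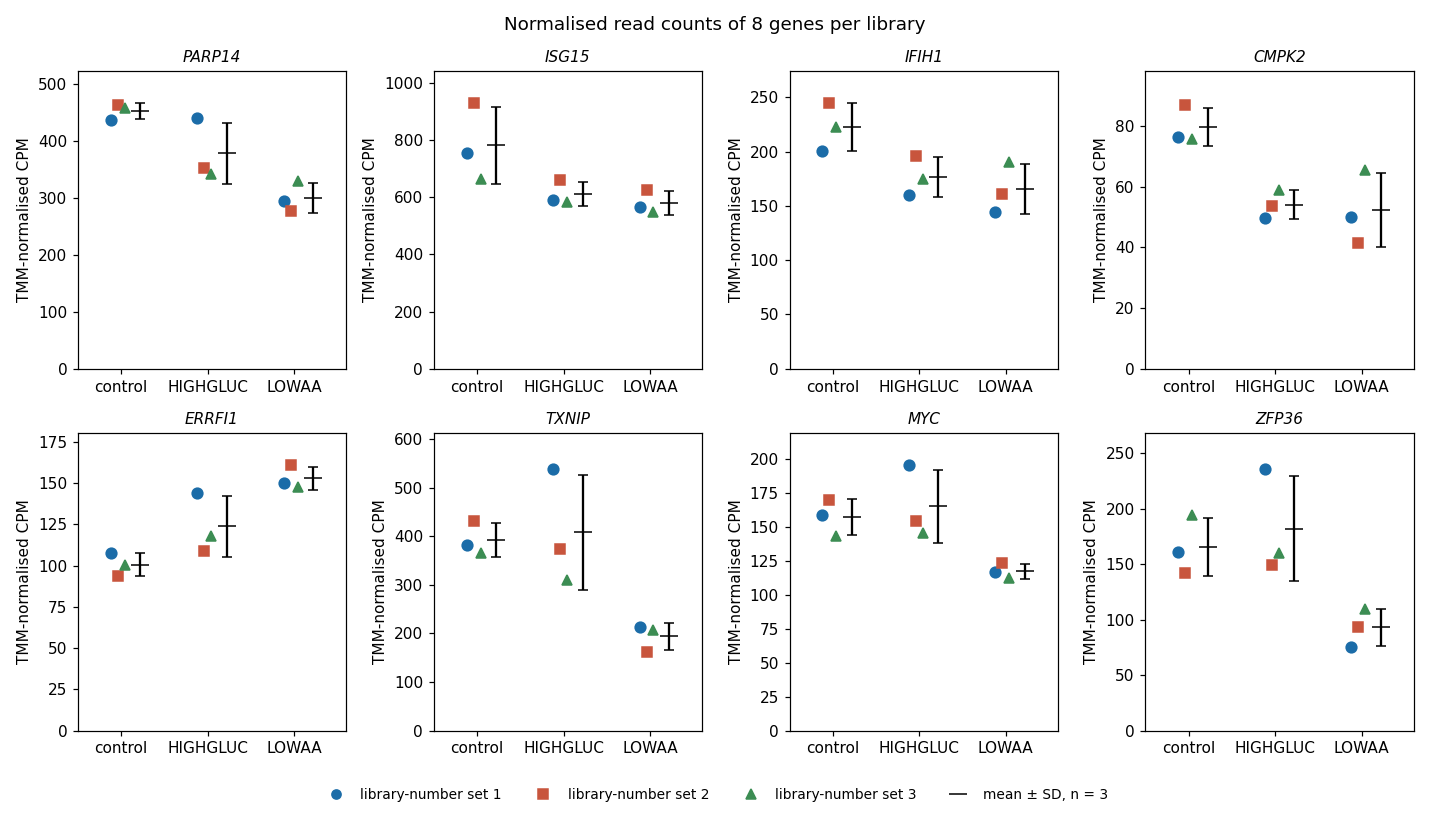
TMM-normalised CPM of 8 genes in each library by group, with symbols for the library-number sets and bars for the mean and SD of 3 libraries. TXNIP, MYC, ZFP36, ERRFI1 and PARP14 in the LOWAA libraries lay outside the range of the control libraries, and HIGHGLUC replicate 6, in set 1, was the highest HIGHGLUC library for TXNIP, MYC and ZFP36.

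The third comparison set HIGHGLUC directly against LOWAA, with no shared control. The immediate early genes, transcription factors and phosphatases induced within minutes of a stimulus, rose as a group in HIGHGLUC relative to LOWAA, with 11 of 14 members higher and a median log2 fold change of 0.42 (camera adjusted p = 0.00230, adjusted p = 0.939 with an estimated correlation). The cell cycle list fell, with 30 of 30 members lower and a median of -0.35 (camera adjusted p = 1.45e-09, adjusted p = 0.939 with an estimated correlation). The amino acid response list fell by a small amount, with 19 of 29 members lower and a median of -0.12 (camera adjusted p = 0.0108, adjusted p = 0.939 with an estimated correlation). The interferon list did not pass (26 of 38 higher, median 0.05). Exact two-sided permutation tests of the scores gave p = 0.40, 0.30 and 0.20 for the immediate early, cell cycle and amino acid response lists.

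Among immediate early genes ZFP36, which destabilises inflammatory mRNAs, had 182 ± 47.2 CPM with HIGHGLUC embryos and 93.0 ± 17.0 CPM with LOWAA embryos (SD, n = 3), a log2 fold change of 0.97 ± 0.20. MYC had a log2 fold change of 0.49 ± 0.11, IER2 of 0.70 ± 0.22 and the phosphatase DUSP1 of 0.37 ± 0.14. Adjusted over the list alone 2 members passed, ZFP36 and MYC, beside 0 over all genes, and with the sets as a term 6 passed, 5 higher and 1 lower. The list score was higher by 0.09, 0.40 and 0.28 in sets 1, 2 and 3, and the call was lost without HIGHGLUC replicate 14 or LOWAA replicate 12 (medians 0.361 and 0.365, camera adjusted p = 0.118 and 0.110). The mitotic genes CDC20, BUB1 and PLK1 had log2 fold changes of -0.52 ± 0.29, -0.41 ± 0.25 and -0.51 ± 0.32. The cell cycle score differed by -0.94, -0.05 and -0.24 in sets 1, 2 and 3, and without HIGHGLUC replicate 6 the median was -0.09 (camera adjusted p = 0.186), while without HIGHGLUC replicate 10 it was -0.69. Adjusted over the list alone 0 cell cycle genes passed without the sets and 9, all lower, with them. In the amino acid response list ATF4 had a log2 fold change of -0.22 ± 0.07, the glycyl-tRNA synthetase GARS of -0.21 ± 0.07, the serine synthesis gene PSAT1 of -0.40 ± 0.15 and CHAC1 of -0.67 ± 0.31. The score of that list differed by -0.19, -0.09 and -0.03 in sets 1, 2 and 3. The call was lost without HIGHGLUC replicate 6, HIGHGLUC replicate 14, LOWAA replicate 8 or LOWAA replicate 12 (medians -0.063, -0.111, -0.099 and -0.084, camera adjusted p = 0.0570, 0.0574, 0.0685 and 0.0813).

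No single gene passed between the HIGHGLUC and LOWAA groups in edgeR. TXNIP had 408 ± 118 CPM against 195 ± 27.7 CPM (SD, n = 3), a log2 fold change of 1.07 ± 0.19, and passed adjusted over the glucose uptake and sensing list alone, a call that was lost with the library-number sets as a term (1.04 ± 0.21, unadjusted p = 0.00442 rather than 0.000293). DLX2 had a log2 fold change of 0.74 ± 0.13, the cyclin gene CCNG2 of 0.77 ± 0.16, the BMP pathway inhibitor SMAD6 of 0.47 ± 0.11 and the kinase PIM3 of 0.85 ± 0.20. Lower genes included the nucleolar proteins GNL3 (-0.45 ± 0.09) and NOP58 (-0.27 ± 0.07), CXCL9 (-0.73 ± 0.18), PAQR8 (-0.45 ± 0.12), the scaffold NEDD9 (-0.33 ± 0.09) and the natriuretic peptide receptor NPR1 (-0.29 ± 0.08). The edgeR test called 0 of 11839 genes (smallest adjusted p = 1.00), with 376 at an unadjusted p under 0.05 where 592 would be expected. The limma-voom count was 0 and the DESeq2 count was 3, among them TXNIP (adjusted p = 1.21e-05) and ZFP36 (0.00100), both higher in HIGHGLUC. With the sets as a term, 956 genes had an unadjusted p under 0.05 in edgeR, above the 592 expected by chance if its p-values are exact. After adjustment it called 17 genes, 9 higher and 8 lower. Among these the growth factor gene PDGFB rose by a log2 fold change of 0.51 ± 0.08 and MYC by 0.49 ± 0.08. The heparanase HPSE fell with -0.72 ± 0.10, the cadherin CDH3 with -0.79 ± 0.15, and the proliferation genes E2F8 and MYBL2 with -0.94 ± 0.18 and -0.58 ± 0.11. In simulated data with 199 changed genes that fit called 16.5 unchanged genes on average and up to 24. That was 8.93% of its calls outside the interferon list there, a share that does not carry over to 17 calls of this fit. Its count was 16 and 40 without HIGHGLUC replicates 6 and 14, and 1, 4 and 5 without LOWAA replicates 8, 12 and 15. Of the 17 genes, 16, 17 and 17 were kept without control replicates 5, 9 and 13. Leaving out HIGHGLUC replicates 6, 10 and 14 kept 3, 10 and 10, and LOWAA replicates 8, 12 and 15 kept 1, 4 and 3.

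Across the 3 groups together edgeR called 0 genes (smallest adjusted p = 1.00), with 350 at an unadjusted p under 0.05, and limma-voom called 0 and DESeq2 called 4, which were ERRFI1, PARP14, TXNIP and ZFP36. With the sets as a term 1051 genes had an unadjusted p under 0.05 in edgeR, and the count of called genes was 24. That count was 57 without control replicate 13, 41, 41 and 48 without HIGHGLUC replicates 6, 10 and 14, and 7 and 15 without LOWAA replicates 8 and 12. Across genes, which are not independent replicates, the log2 fold changes of HIGHGLUC and LOWAA against the control had a correlation of 0.793. Shared control libraries alone gave 0.501 on average in 20 simulations, with a range of 0.430 to 0.597. The share of genes with the same sign in both was 66.4%, within the range of 66.2% to 68.0% in the simulations. With the sets as a term it was 66.3%, below the simulated 66.7% to 67.8%. The correlation lay above every simulation, with the sets as a term too (0.695, highest simulated 0.643). So did the covariance (0.0912, highest simulated 0.0724, and with the sets 0.0684, highest simulated 0.0491). The simulations drew each gene independently and so lack variation shared between genes. Their ranges therefore do not decide whether the agreement exceeds what shared controls give. No gene was called against the control in both, and with the sets as a term cytb and ATP8B4 were, where the simulations gave 1.05 such genes on average and up to 5.

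The table also holds the authors' own calls from Baggerley's test. These number 11 genes for HIGHGLUC against control, 77 for LOWAA against control and 44 for LOWAA against HIGHGLUC. They include the interferon genes CMPK2 and DTX3L for HIGHGLUC, and HERC6, PARP14, TXNIP, CHAC1, MYC and ERRFI1 for LOWAA. All 11, 77 and 44 had the same direction in edgeR here, and 9, 58 and 38 had an unadjusted p under 0.05. These values come from the same libraries and are not independent evidence.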

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

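The intron test was chosen after the values were seen. Intron reads, outside the main measurement, made up 13.7% of the gene reads of LOWAA replicate 12 (95% Wilson interval 13.68% to 13.73%), above the highest control library at 10.5%. Both other LOWAA libraries lay below that control library. The edgeR test on intron reads called 0 of 9713 genes in each comparison, with 315, 667 and 747 at an unadjusted p under 0.05 for HIGHGLUC against control, LOWAA against control and HIGHGLUC against LOWAA, and no other tool was run on them. No biological explanation was tested.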

How the results depend on the processing

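All alternatives of the fit with sets and of the list medians, unique exon reads, the term for multiply matched reads and limma-trend on the deposited normalised values were chosen after the result was seen; the others were planned. Without sets, edgeR called 0 genes under every other scaling, filter, covariate and test setting except DESeq2, which called 4 for LOWAA against control, 3 for HIGHGLUC against LOWAA and 4 across the groups, and the sets term, which called 3 for HIGHGLUC against control, 19 for LOWAA against control, 17 for HIGHGLUC against LOWAA and 24 across the groups. The cause was not tested. The overlap of calls against the control rose from 0 to 2 with sets. Leaving out each library gave 0 to 0, 0 to 1 and 0 to 0 genes in the 3 comparisons, 0 to 0 across the groups and 0 to 0 for the overlap. The self-test recovered 80.3% of 2-fold changes at this depth and spread and 28.4% of 1.5-fold changes. Those rates come from 1 simulated data set with 199 changed genes, each drawn independently. They do not carry over to data in which few genes changed. With sets, unique exon reads gave 7, 57, 36 and 60 calls in the same order, DESeq2 gave 21, 40, 30 and 59, and a further term for multiply matched reads gave 0, 46, 23 and 46. Of the 19 LOWAA calls 19, 18 and 19 were kept there, of the 3 HIGHGLUC calls 3, 3 and 0, and of the 17 calls between these groups 17, 14 and 10. Without 1 library the counts with sets ran from 0 to 31, 2 to 39, 1 to 40 and 7 to 57. The lowest for LOWAA against control was without LOWAA replicate 12, and the lowest for HIGHGLUC against LOWAA was without LOWAA replicate 8. These fits kept 1 to 19 of the 19 LOWAA calls, 0 to 3 of the 3 HIGHGLUC calls and 1 to 17 of the 17 between these groups. An estimated correlation gave 0, 0 and 0 lists in place of 4, 3 and 3, and sets gave 4, 5 and 4. Sets added the cell cycle (higher, camera adjusted p = 0.0276) and immediate early genes (lower, 0.04999) for LOWAA against control and autophagy and lysosome (higher, 0.0345) for HIGHGLUC against LOWAA, each with an adjusted p of 0.821 with an estimated correlation. In set 2 the scores of the LOWAA lists went the other way: they differed by 0.32, -0.08 and 0.15 in sets 1, 2 and 3 for the cell cycle and by -0.25, 0.30 and -0.38 for the immediate early genes. Without 1 library 1 to 6, 2 to 5 and 1 to 5 lists were called. Of the medians of called lists, that of the cell cycle for HIGHGLUC against control reversed, to 0.0070 without HIGHGLUC replicate 6, with a range of -0.58 to 0.0070 over these fits. The interferon list kept its call in 9 of 9 such fits in both comparisons with the control, with medians from -0.32 to -0.21 and from -0.38 to -0.26. The planned change of pseudocount was not run, since counts were the unit tested.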

Other observations

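The tests of sets between libraries, of the 27 choices of control libraries, and of depth, shared reads, leukocyte RNA and single control libraries were chosen after the result was seen; the splits of the libraries were planned. The sets of library numbers differed from each other in many genes. With the group in the fit, edgeR called 1202 of 11839 genes between sets, 1107 of them with at least 90% unique reads. FOSB, an immediate early transcription factor, had 14.5 ± 8.29 CPM in set 3 (SD over its 3 libraries) against 1.11 ± 0.38 in set 1 and 0.719 ± 0.129 in set 2 (edgeR adjusted p = 8.73e-09). IgFBp3, which binds insulin-like growth factors, had 73.6 ± 9.38 CPM in set 1 against 25.1 ± 3.47 and 27.5 ± 3.52 in sets 2 and 3. The matricellular gene NOV had 1255 ± 84.4 CPM in set 1 against 628 ± 31.6 and 724 ± 36.1. The cholesterol exporter ABCA1 had 29.4 ± 2.74 and 24.2 ± 3.65 CPM in sets 1 and 2 against 8.24 ± 2.44 in set 3. The scavenger receptor SCARA5 had 9.91 ± 2.18 CPM in set 1 against 1.27 ± 0.62 and 1.43 ± 0.26. SPP1, a secreted ligand of integrins, had 4098 ± 505 CPM in set 1 against 3155 ± 130 and 2708 ± 285. Of the lists, 11 of 30 cell cycle genes, 11 of 38 interferon genes and 10 of 12 mitochondrial genes differed between sets in that test. What the sets stand for is not in the labels.

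The interferon list was lower in both embryo treatment groups than in the control. A single control library is argued against, since the median closest to 0 without one was -0.212, as are reads shared between similar genes, with -0.263 for unique exon reads. Leukocyte RNA in the control libraries stays open. There 0 reads of PTPRC allow at most 0.110 CPM and 8 of 10 listed leukocyte genes were under 1 CPM, but CD163 had 10.7 CPM, with 12.5, 12.9 and 7.36 CPM in control replicates 5, 9 and 13 against 5.63 to 8.56 CPM in the 6 other libraries. CD14 had 4.85, 3.36 and 5.52 CPM in these control libraries against 3.81 to 8.30 CPM in the 6 others, which goes the other way. Of the 27 ways to take 1 library per set as the control, only the real 1 gave a difference as large (0.308, highest other 0.231), but the list was picked because it stood out, and for 3 of the 26 lists the real choice was the largest where 0.963 would be by chance. The others were the mitochondrial list and smooth muscle, a cell type list, with -0.229 for the control minus the rest (highest other 0.228 in size). Chance, leukocyte RNA and an unrecorded difference of the control cultures therefore stay open beside a weaker interferon signal from the HIGHGLUC and LOWAA embryos, which is a hypothesis that was not tested.

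The mitochondrially encoded genes were higher in both groups than in the control. Reads matching several places are argued against for cytb, ND3 and ND5, which had 100% unique reads. For such genes unique exon reads could hardly change the result, so the smaller median of 0.218 with them adds little. Reads of nuclear copies that matched a single place were not tested. Depth is argued against because the difference was at least 0.272 in both the set with the shallowest and the set with the deepest control library. In set 3 it was 0.128. Control replicate 9 may account for much of the pattern, since without it the call for HIGHGLUC ended (camera adjusted p = 0.299, median 0.080). The call for LOWAA ended without it too (camera adjusted p = 0.122, median 0.171). Of the 27 choices 1 gave a difference as large, the real 1 (-0.300, highest other 0.261 in size), which for a list picked from 26 leaves chance open beside an effect of the embryos.

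The libraries parted by their share of multiply matched reads, with replicates 5, 6, 8 and 10 on one side. The 89 genes that parted them included FILIP1L, with 406 ± 33.1 CPM in those 4 libraries and 0.294 ± 0.149 CPM in the 5 others, and TPT1, with 1.74 ± 0.58 against 190.0 ± 20.9 CPM. Of these genes 100% had under 90% unique reads beside 5.50% of 11750 others, which is consistent with overlapping or near-identical genes being given reads differently between libraries. The line between the libraries ran through set 2, with replicate 10 on one side and replicates 9 and 12 on the other. No biological explanation was tested.

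Regrouping the libraries tested the counts. The 10 splits of 6 libraries are too few for a share under 0.05. Without sets the real counts of genes were 0, 0 and 0 and the highest other splits gave 1, 0 and 9 for HIGHGLUC against control, LOWAA against control and HIGHGLUC against LOWAA. With sets the real counts were 3, 19 and 17 and the highest others 23, 14 and 23. Those highest splits placed libraries of the same set in 1 group. Splits that kept 1 library of each group in every set gave at most 2, 0 and 0 genes. They are too few to decide on chance. The real counts of lists were 4, 3 and 3 and the highest others 9, 8 and 7. Across the 3 groups without sets the real count was 0, which all 100 drawn splits reach by definition, so they decide nothing on chance. The highest other gave 217 genes, which points to a structure of the samples. With sets 1 of the 36 relabellings within sets, the real 1, gave 24 genes and the highest other gave 11. That share is under 0.05, but it is the smallest the relabellings allow and belongs to 1 of several counts regrouped here. It argues against chance for that count without excluding it. The relabelling leaves open which of the genes changed, and it does not cover the single comparisons.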
